A study of Danio rerio with 4 samples.

How the data were processed

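RNA was sequenced from cells sorted by flow cytometry from the tail region of zebrafish (Danio rerio) embryos at 52 hours post fertilisation (hpf). The tail at this stage holds the caudal hematopoietic tissue (CHT), a vascular site in which blood stem and progenitor cells lodge and expand. Cells carrying mCherry under the kdrl promoter, a reporter of endothelial cells, made up the group CHT-EC, and cells carrying GFP under the CD41 (itga2b) promoter, a reporter of hematopoietic stem and progenitor cells and of thrombocytes, made up the group CHT-HSPC. There were 2 libraries per group. Nothing in the labels says whether the libraries of a group came from separate clutches or sorts, so the p-values measure only the spread between these samples, which may be technical.

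The authors deposited 1 table of counts per Ensembl gene, with a column for each of the 4 libraries. They were taken as not normalised, because they were whole numbers and the column totals differed. The labels' protocols mention a normalization before testing, which these columns do not show, and whether single mates or read pairs were counted was not given in the sources used here. All columns were tied to a sample by name: the table writes HSC where the sample titles write HSPC, and the replicate numbers match. Per the labels' protocols, total RNA was isolated with a column kit, libraries were made with NEBNext Ultra, a kit for mRNA that does not mark strand in its standard form, and 150 bp paired-end reads were generated on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools were TopHat2, whose version was not given in the sources used here, and HTSeq 0.6.1, with the genome build GRCz10. The annotation release, the strand setting and the handling of reads that map to several genes were not given in the sources used here. The labels' protocols also name DEGseq, whose model has no term for the spread between replicates, so a test based on replicates was used here. No genome of the build GRCz10 was used here, so genes are given by symbol and Ensembl identifier and no coordinates are printed. Symbols are those paired with the identifiers in the deposited table, where 709 symbols belong to more than 1 identifier.

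Counting by gene affects the values of gene families. Near-identical copies, such as the embryonic hemoglobin genes (hbae and hbbe), the fast muscle myosins (myhz), the hsp70 genes and the mpeg1 pair, share reads that the authors' counting could split or drop, so the level of a single member is uncertain. Counts of overlapping genes and of antisense partners cannot be told apart where strand was not used. The reads carried no molecular identifiers, so intervals and floors cover counting error only.

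The totals were 27514202 and 29684676 counts for CHT-EC replicates 1 and 2, and 30667842 and 32268535 for CHT-HSPC replicates 1 and 2. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.112, 0.102, 0.101 and 0.0867 CPM (counts scaled to a common library total) in the same order. Of 31947 genes listed, 7008 had no count in any library. The filter of edgeR (filterByExpr with its default minimum count of 10 and minimum total of 15) left 19016 genes for testing. Levels are given as CPM with library sizes scaled by TMM, as mean ± SD with n = 2 libraries per group. TMM factors were 0.971, 0.992, 0.968 and 1.07.

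The main comparison was CHT-EC against CHT-HSPC with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, without a block, adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p in the text comes from this test unless another is named. The log2 fold change is CHT-EC minus CHT-HSPC, so a negative value means a higher level in CHT-HSPC, and the SE is the absolute log2 fold change divided by the square root of F. For a gene with 1 to 3 counts in a group, the ratio of summed counts is given with an exact (Clopper-Pearson) binomial interval at the 95% level. The spread between libraries of a group was wide, with a biological coefficient of variation of 0.540. The test was tested on simulated data drawn from the means and library sizes of these samples, with 200 changed genes among 18067. It called 44 of 100 genes with a log2 change of 2, 90 of 100 with a log2 change of 4, and 3 of 17867 unchanged genes. Each simulated gene took the dispersion of the fitted trend, and no group of genes was shifted in a single library. Genes that vary more than the trend, and shifts between replicates, were therefore not covered. Recovery and error in the real data may be worse.

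A set of 25 gene lists covering cell types, niche signals and cell states was fixed before the data were examined, 23 of them by symbol and 2 (ribosomal proteins and mitochondrial genes) by the form of the symbol. Each list is described by the number of members past the threshold over all genes tested and by the number past it when adjusted over the list alone. Lists could share genes: of the tested members, 2 of 18 neutrophil, 3 of 18 macrophage, 8 of 13 thrombocyte and 2 of 19 erythroid genes also stood in another list. The 23 lists with at least 5 tested members were compared with all other genes by camera from limma 3.58.1 with an inter-gene correlation of 0.01, on log-CPM with a prior count of 2, and again with an estimated correlation. The self-contained test fry was run beside them. In the simulation camera with the fixed correlation called the 1 changed list, all of whose genes were raised, and none of 20 unchanged lists. The simulated genes varied independently, while the estimated correlation of the real lists ran from −0.0243 (thrombocyte) to 0.985 (skeletal muscle). The simulation therefore does not show how often camera calls a correlated list by error. Neither camera with an estimated correlation nor fry was simulated, so their power is not known. With 2 libraries per group the correlation is estimated from little spread within groups. A list that is not called with it is therefore not shown to be unchanged.

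The rule for named genes was also fixed before the data were examined. It took every gene of the sort reporter and study candidate lists, and in each direction the 4 genes with the largest change past the threshold that had a gene symbol other than a clone name and a mean of at least 20 CPM in the higher group. It also took the 2 members of each list with the largest change past the threshold and a mean of at least 5 CPM in the higher group, or the member with the highest mean where none passed. Other genes named are members of these lists, or are said to have been chosen after their values were seen.

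The alternatives were DESeq2 size factors, upper-quartile factors or totals alone in place of TMM, no low-count filter, a filter of at least 10 CPM in 2 libraries, the replicate number as a block, hemoglobin genes left out, each library left out in turn, the Wald test of DESeq2 1.42.0, limma-voom, a 2-fold minimum and an adjusted p threshold of 0.01. When 1 library was left out, the lone library of its group was assumed to vary like the other group. Counts of list members without each library were added after seeing the data. Random gene lists were drawn with a fixed seed within bins of mean log-CPM over the 4 libraries. Replicates of a group were compared before averaging, and neither pair agreed within sampling noise, with a chi-square per degree of freedom of 147 for CHT-EC and 134 for CHT-HSPC.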

Results

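Gene expression was measured by RNA sequencing in kdrl:mCherry-positive cells (CHT-EC, 2 libraries) and CD41:GFP-positive cells (CHT-HSPC, 2 libraries) sorted from the tail of zebrafish embryos at 52 hpf. The gates select for endothelial cells of the caudal hematopoietic tissue, which form part of the niche, and for the blood stem and progenitor cells that reside there. Transcripts of the endothelial list took 0.0672% and 0.0504% of CHT-EC counts and 0.0416% and 0.0438% of CHT-HSPC counts. The groups are therefore named by gate, and a difference between them is not a difference between pure cell types. Library totals ranged from 27514202 to 32268535 counts, and between 19598 and 23309 genes had a count. Across genes, the Pearson correlation of log2 values was 0.916 between the CHT-EC libraries and 0.905 between the CHT-HSPC libraries, against 0.816 to 0.839 for pairs from different groups. Genes are not independent replicates, so these correlations only describe the libraries.

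As a whole, no fixed list was called with an estimated correlation, which 2 libraries per group estimate poorly. By single members, 14 of 18 neutrophil, 9 of 18 macrophage and 8 of 19 erythroid genes were higher in CHT-EC. Higher in CHT-HSPC were 4 of 13 thrombocyte genes, among them itga2b, the gene behind the CD41 reporter. In the same order these counts were 8, 3, 7 and 1 without CHT-EC replicate 1. In all, 718 genes were higher in CHT-EC and 143 were higher in CHT-HSPC among the 19016 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and all 861 differed by at least 2-fold. Among genes with a symbol other than a clone name and a mean of at least 20 CPM in the higher group, those with the largest changes toward CHT-EC were ccl34a.4 (ENSDARG00000090873), a chemokine gene, grna (ENSDARG00000004954), a granulin gene, il1fma (ENSDARG00000089383), an interleukin-1 family member, and mpeg1.1 (ENSDARG00000055290), a macrophage perforin. The counts of ccl34a.4 were 3966 and 1443 in CHT-EC against 0 and 1 in CHT-HSPC, a ratio of 6195 with a counting interval of 1111 to 244732 (adjusted p = 0.00575). The level of grna was 35.3 ± 9.91 CPM in CHT-EC and 0.0723 ± 0.102 CPM in CHT-HSPC (mean ± SD, n = 2 libraries throughout; adjusted p = 0.00945), and that of il1fma was 23.1 ± 21.8 against 0.0867 ± 0.123 CPM (adjusted p = 0.0249). The HSPC values of grna and il1fma rest on 5 and 6 counts. Under the same limits, the largest changes toward CHT-HSPC were those of PDGFD (ENSDARG00000077677), a platelet-derived growth factor (log2 fold change −3.56, SE 0.57, adjusted p = 0.0236), itgb3b (ENSDARG00000045070), an integrin beta chain (−3.49, SE 0.44, adjusted p = 0.0130), aqp1a.2 (ENSDARG00000091027), an aquaporin (−3.36, SE 0.52, adjusted p = 0.0216), and itga2b. The count of calls rested heavily on CHT-EC replicate 1, without which 111 genes were higher in CHT-EC and 10 in CHT-HSPC. Without it il1fma (adjusted p = 0.172), PDGFD (0.0833), itgb3b (0.0830) and aqp1a.2 (0.127) were no longer past the threshold, and PDGFD was also lost without CHT-EC replicate 2 (0.0672). Without CHT-EC replicate 2 the counts were 573 and 61. They were 471 and 103 with totals alone, 2119 and 812 without the low-count filter, 2075 and 746 with DESeq2 and 705 and 233 with limma-voom. With limma-voom the calls of ccl34a.4 (0.126), grna (0.0664) and il1fma (0.257) ended as well.

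The gene behind the CD41 reporter separated the groups, and the gene behind the kdrl reporter did not pass the test. The level of itga2b (ENSDARG00000018687), the integrin alpha IIb of stem cells and thrombocytes, was 71.6 ± 21.7 CPM in CHT-HSPC and 7.0 ± 3.27 CPM in CHT-EC (log2 fold change −3.35, SE 0.46, adjusted p = 0.0158). That of kdrl (ENSDARG00000105215), a VEGF receptor of endothelial cells, was 8.93 ± 7.83 CPM in CHT-EC and 1.98 ± 1.53 CPM in CHT-HSPC (log2 fold change 2.17, SE 0.92, adjusted p = 0.208). The kdrl counts were 386 and 100 in CHT-EC and 91 and 31 in CHT-HSPC, so CHT-EC replicate 2 (3.40 CPM) lay near CHT-HSPC replicate 1 (3.07 CPM). Of these 2 reporter genes, 1 passed over all genes, and both passed when adjusted over the list alone. The call of itga2b ended without CHT-EC replicate 1 (adjusted p = 0.0743), and kdrl passed without the low-count filter (adjusted p = 0.0240).

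**Figure D1:**
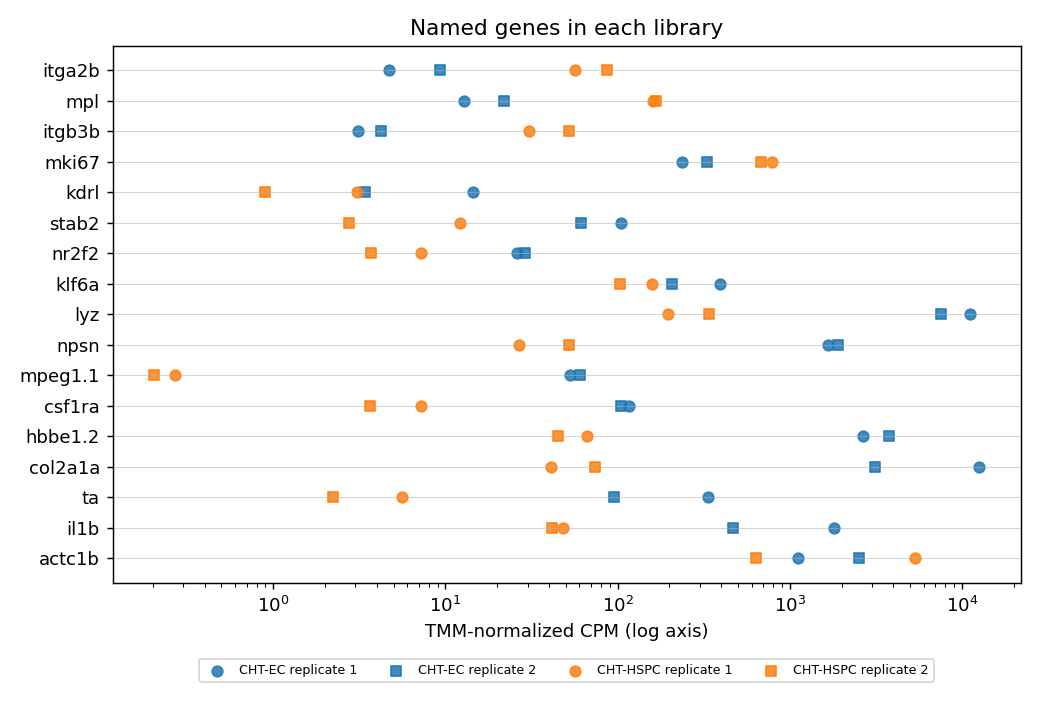
TMM-normalised CPM on a log axis for named genes (rows) in each library, with CHT-EC in blue and CHT-HSPC in orange, circles for replicate 1 and squares for replicate 2. The CHT-HSPC libraries lie above both CHT-EC libraries for itga2b, mpl, itgb3b and mki67, kdrl in CHT-EC replicate 2 (3.40 CPM) lies next to CHT-HSPC replicate 1 (3.07 CPM), and actc1b is highest in CHT-HSPC replicate 1.

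Endothelial identity genes leaned toward CHT-EC at low levels, and none of the 25 tested members passed over all genes in the edgeR test with TMM factors and its default filter, where 14 members higher in CHT-EC and 1 higher in CHT-HSPC had an unadjusted p under 0.05. Their median log2 fold change was 1.92, with 22 of 25 on the CHT-EC side, and 8 were higher in CHT-EC when adjusted over the list alone, among them egfl7 (4.69), a secreted factor of vessels, and pecam1 (2.79), an endothelial junction protein. DESeq2 placed 12 members higher in CHT-EC and 1 higher in CHT-HSPC, and limma-voom placed none. The edgeR test with the replicate number as a block placed 4 higher in CHT-EC. The list stood above other genes by camera (adjusted p = 0.0031), but not with an estimated correlation (adjusted p = 0.72) and not without CHT-HSPC replicate 2 (adjusted p = 0.0698). The camera call was also lost with the filter of at least 10 CPM, where the median was 0.52 (adjusted p = 0.425). The median level of its members was 19.9 and 7.34 CPM in CHT-EC replicates 1 and 2 and 3.91 and 3.56 CPM in CHT-HSPC. The number of members higher in CHT-EC was 14 without the low-count filter, 5 without CHT-EC replicate 2, and 1 with upper-quartile factors, with the filter of at least 10 CPM (8 tested) or without CHT-HSPC replicate 1. The median was 0.90 without CHT-EC replicate 1. The member with the highest level, fli1a (ENSDARG00000054632), a transcription factor of endothelium and thrombocytes, was at 191 ± 56.7 CPM in CHT-EC and 231 ± 11.1 CPM in CHT-HSPC (log2 fold change −0.27, SE 0.29, adjusted p = 0.616), with a value of 0.00846 without CHT-EC replicate 1.

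Genes of venous and scavenger endothelium were higher in CHT-EC for 2 of 15 tested members over all genes and for 6 when adjusted over the list alone. The level of stab2 (ENSDARG00000045748), a hyaluronan scavenger receptor of the caudal vein, was 82.9 ± 30.5 CPM in CHT-EC and 7.46 ± 6.66 CPM in CHT-HSPC (log2 fold change 3.48, SE 0.70, adjusted p = 0.0432). That of nr2f2 (ENSDARG00000040926), a regulator of venous identity, was 27.6 ± 2.04 against 5.46 ± 2.53 CPM (log2 fold change 2.34, SE 0.47, adjusted p = 0.0415). The list median was 1.56, with a camera adjusted p of 0.0015 and an adjusted p = 0.72 with an estimated correlation. Without CHT-EC replicate 1 neither gene passed (0.177 for stab2 and 0.157 for nr2f2), nr2f2 was also lost without CHT-EC replicate 2 (0.115) or CHT-HSPC replicate 2 (0.0714), and both missed the threshold narrowly with totals alone (0.0512 each). Without CHT-HSPC replicate 1, 3 members passed. No member of the arterial and Notch list (14 tested, median 0.37) passed, over all genes or over the list alone, in the edgeR test, where 5 members higher in CHT-EC had an unadjusted p under 0.05, while DESeq2 placed 2 members higher in CHT-EC and limma-voom none. Over all genes, 2 members were higher in CHT-EC and 1 in CHT-HSPC without the low-count filter, 1 was higher in CHT-EC with the filter of at least 10 CPM, and 2 were without CHT-EC replicate 2. With the replicate number as a block, 1 member was higher in CHT-EC. The camera adjusted p of the arterial list was 0.228. The median was 0.68 without CHT-EC replicate 2 (camera adjusted p = 0.0208) and 0.75 without CHT-HSPC replicate 2 (0.254). Its most abundant member, the Notch receptor notch1b (ENSDARG00000052094), was at 187 ± 46.1 CPM in CHT-EC and 339 ± 175 CPM in CHT-HSPC (adjusted p = 0.246, and 0.0452 without the low-count filter).

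The stem and progenitor list split between the groups, with 4 of 23 members higher in CHT-EC and 5 higher in CHT-HSPC. Adjusted over the list alone the counts were 4 and 10. Over all genes they were 2 and 4 with totals alone, 4 and 7 with DESeq2 and 4 and 6 with limma-voom. The members higher in CHT-HSPC were itga2b, zfpm1 (−2.40), a cofactor of GATA factors, runx1 (−1.89) and myb (−1.60), both required for definitive blood stem cells, and meis1b (−1.43). The members higher in CHT-EC were fcer1gl (ENSDARG00000104077), an Fc receptor gamma chain of myeloid cells, coro1a (2.51) and ptprc (1.63), both pan-leukocyte genes, and meis1a (2.64), a homeobox gene. The level of fcer1gl was 220 ± 39.5 CPM in CHT-EC and 6.99 ± 1.22 CPM in CHT-HSPC (log2 fold change 4.98, SE 0.33, adjusted p = 0.00357). Camera did not call the list (adjusted p = 0.130). Only fcer1gl passed without CHT-EC replicate 1, 2 members were higher in CHT-EC without each of the other libraries, and runx1 was also lost without CHT-EC replicate 2 (adjusted p = 0.169) or CHT-HSPC replicate 2 (0.133). The calls of myb (0.0534) and meis1b (0.0894) also ended without CHT-EC replicate 2, and ptprc and meis1a were lost whichever library was left out, with an adjusted p of 0.0543 to 0.146 for ptprc and 0.0572 to 0.236 for meis1a. In the same libraries, transcripts of the neutrophil list took 2.83% and 2.34% of CHT-EC counts and 0.251% and 0.334% of CHT-HSPC counts.

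Thrombocyte genes were higher in CHT-HSPC for 4 of 13 members over all genes and for 8 when adjusted over the list alone, and none was higher in CHT-EC, except 1 without CHT-EC replicate 2 and 1 without the low-count filter. Those higher in CHT-HSPC were itga2b, itgb3b, mpl and gp1bb (−2.11), a platelet glycoprotein. The sort on CD41:GFP selects for itga2b, so its direction here and in the stem and adhesion lists follows from the gate. The level of mpl (ENSDARG00000039222), the thrombopoietin receptor, was 164 ± 5.0 CPM in CHT-HSPC and 17.4 ± 6.48 CPM in CHT-EC (log2 fold change −3.24, SE 0.35, adjusted p = 0.0101), and that of itgb3b was 41.3 ± 15.1 against 3.68 ± 0.804 CPM. The median over the list was −1.38, with a camera adjusted p of 0.0015 and an adjusted p = 0.52 with an estimated correlation. Only mpl passed without CHT-EC replicate 1. Cell cycle genes lay on the CHT-HSPC side for 34 of 41 members, with a median of −0.57 (camera adjusted p = 0.000168, and adjusted p = 0.72 with an estimated correlation), or −0.34 without CHT-EC replicate 1 and −0.28 without CHT-HSPC replicate 1. Of the members higher in CHT-HSPC, 2 passed over all genes and 4 when adjusted over the list alone. The proliferation marker mki67 (ENSDARG00000091150) was at 733 ± 70.7 CPM in CHT-HSPC and 283 ± 68.1 CPM in CHT-EC (log2 fold change −1.37, SE 0.27, adjusted p = 0.0415), and the kinetochore gene cenpf (ENSDARG00000055133) was at 193 ± 1.53 against 72.8 ± 21.2 CPM (log2 fold change −1.41, SE 0.29, adjusted p = 0.0470). Both calls lay near the threshold, and cenpf missed it with upper-quartile factors (0.0508) and with totals alone (0.0545). With the replicate number as a block, 0 cell cycle members passed. With 1 library left out, cenpf was lost in every case and mki67 in every case but that without CHT-HSPC replicate 2. Such fits leave a lone library in a group, so these losses cannot be told apart from a loss of power. In the single libraries mki67 was at 235 and 332 CPM in CHT-EC and 783 and 683 CPM in CHT-HSPC.

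Neutrophil genes and 9 of 18 macrophage genes were higher in CHT-EC. These lists had the smallest camera p-values of the 23 tested with a fixed correlation, and neither was called with an estimated one (adjusted p = 0.66 and 0.52). Of 18 neutrophil and myeloid genes, 14 were higher in CHT-EC, none was higher in CHT-HSPC, and all 18 were higher when adjusted over the list alone. The level of lyz (ENSDARG00000057789), lysozyme, was 9320 ± 2489 CPM in CHT-EC and 267 ± 101 CPM in CHT-HSPC (log2 fold change 5.12, SE 0.39, adjusted p = 0.00484). That of npsn (ENSDARG00000010423), a neutrophil protease, was 1792 ± 173 against 39.5 ± 18.04 CPM (log2 fold change 5.50, SE 0.41, adjusted p = 0.00484). The median of these genes was 3.0, with a camera adjusted p of 5.35e-11. Of 18 macrophage genes, 9 were higher in CHT-EC over all genes and 12 when adjusted over the list alone, with a median of 3.53 (camera adjusted p = 2.99e-08). The median was the same with the 3 complement genes at 0 counts in CHT-HSPC set to the bound that 3 counts over the group allow. The level of mpeg1.1 was 56.8 ± 5.36 CPM in CHT-EC and 0.236 ± 0.0476 CPM in CHT-HSPC (log2 fold change 7.90, SE 0.45, adjusted p = 0.00357). Without CHT-EC replicate 1, 8 neutrophil and 3 macrophage members were higher in CHT-EC, and with limma-voom 5 macrophage members were.

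Hemoglobin transcripts were higher in CHT-EC, while the erythropoietin receptor was higher in CHT-HSPC. Of 19 erythroid genes, 8 were higher in CHT-EC and 1 in CHT-HSPC, and 9 and 1 when adjusted over the list alone. The members higher in CHT-EC were 6 embryonic globin genes, alas2 (4.55), the first enzyme of red cell heme synthesis, and cahz (4.71), a red cell carbonic anhydrase. The level of hbbe1.2 (ENSDARG00000090689) was 3208 ± 792 CPM in CHT-EC and 55.5 ± 14.9 CPM in CHT-HSPC (log2 fold change 5.85, SE 0.36, adjusted p = 0.00357), and that of hbbe3 (ENSDARG00000038147) was 792 ± 332 against 22.0 ± 26.6 CPM (log2 fold change 5.17, SE 1.11, adjusted p = 0.0496). These globin genes are near-identical copies, so their single values are uncertain. The receptor epor had a log2 fold change of −1.78 (adjusted p = 0.0379). Hemoglobin genes took 1.63% and 2.94% of CHT-EC counts and 0.109% and 0.0472% of CHT-HSPC counts. The erythroid median was 1.08, with a camera adjusted p of 0.0030 and an adjusted p = 0.72 with an estimated correlation. Camera lost the call with hemoglobin genes left out (median 0.26, adjusted p = 0.406) and without CHT-EC replicate 2 (median 0.70, adjusted p = 0.133). The call of hbbe3 ended without CHT-EC replicate 1 (0.131), without CHT-EC replicate 2 (0.0889) and with totals alone (0.0577), and that of epor ended without CHT-EC replicate 1 (0.149) or CHT-HSPC replicate 1 (0.0572), while 2 members were higher in CHT-HSPC without CHT-EC replicate 2.

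**Figure D2:**
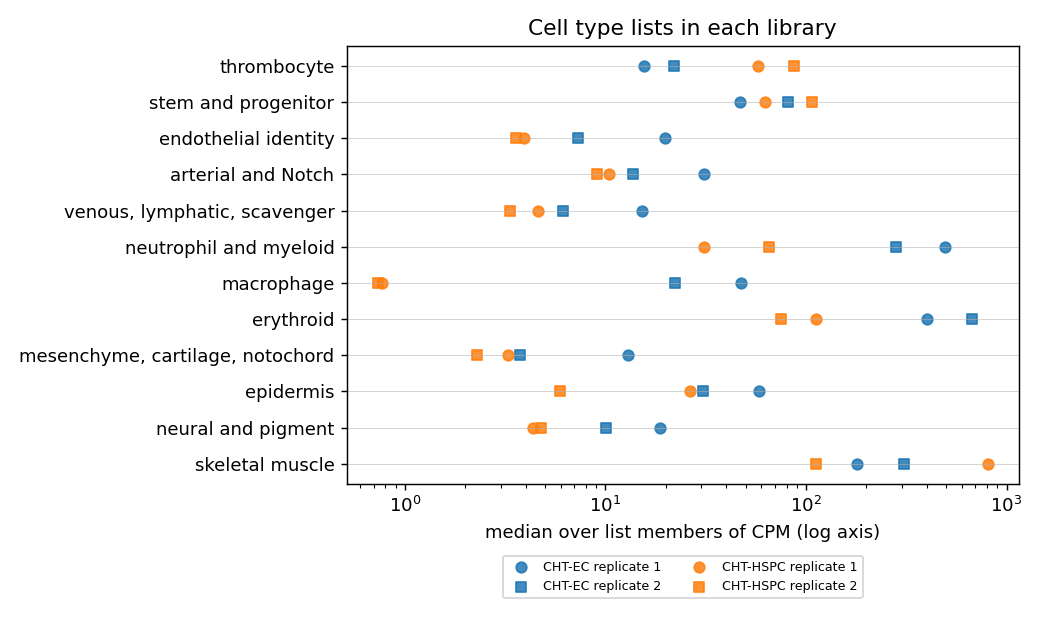
Median CPM over the members of each cell type list (rows) on a log axis, in each library, with CHT-EC in blue and CHT-HSPC in orange, circles for replicate 1 and squares for replicate 2. The neutrophil medians are 493 and 281 CPM in CHT-EC against 31.0 and 65.1 CPM in CHT-HSPC, while the skeletal muscle median is highest in CHT-HSPC replicate 1, at 808 CPM.

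Among secreted niche factors, 5 of 42 tested genes were higher in CHT-EC and 1 was higher in CHT-HSPC, and 8 and 1 when adjusted over the list alone. The members higher in CHT-EC were the granulocyte colony-stimulating factors csf3a (ENSDARG00000102211) and csf3b (ENSDARG00000098752), il34 (3.38), a ligand of the macrophage receptor Csf1r, ctgfa (4.28), a connective tissue growth factor, and wnt11r (3.84). The level of csf3b was 137 ± 146 CPM in CHT-EC and 5.03 ± 0.896 CPM in CHT-HSPC (log2 fold change 4.77, SE 0.89, adjusted p = 0.0361), and that of csf3a was 48.0 ± 54.1 against 0.303 ± 0.429 CPM (log2 fold change 7.34, SE 1.56, adjusted p = 0.0491). Both were several times higher in CHT-EC replicate 1 than in replicate 2, at 240 against 33.6 CPM for csf3b and 86.2 against 9.79 CPM for csf3a. The member higher in CHT-HSPC was angpt1 (−1.70), an angiopoietin. The niche median was 1.44, with a camera adjusted p of 0.0030 and an adjusted p = 0.72 with an estimated correlation. Only il34 passed without CHT-EC replicate 1, where the median was 0.59 (camera adjusted p = 0.130), and camera also lost the call without CHT-HSPC replicate 2 (adjusted p = 0.10), while 9 members were higher in CHT-EC without CHT-EC replicate 2. The call of csf3a also ended with DESeq2 (0.0541), limma-voom (0.362) and totals alone (0.0606), and that of csf3b with limma-voom (0.0764), without CHT-HSPC replicate 1 (0.0518) and without CHT-HSPC replicate 2 (0.0634). Single libraries also decided ctgfa (0.0699 without CHT-HSPC replicate 2), wnt11r (0.134 without CHT-EC replicate 2) and angpt1 (0.124 without CHT-EC replicate 2 and 0.0838 without CHT-HSPC replicate 1). In the same libraries the neutrophil, macrophage and notochord lists had medians of 3.0, 3.53 and 1.77 toward CHT-EC, so the cells that made these transcripts are not known from these values.

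Of 34 cytokine and chemokine receptors, 1 was higher in CHT-EC and 2 were higher in CHT-HSPC, and 2 and 3 when adjusted over the list alone. Higher in CHT-EC were 3 without CHT-EC replicate 2, 4 without CHT-HSPC replicate 2, 6 with DESeq2 and 7 without the low-count filter, and higher in CHT-HSPC was 1 without either replicate 1, 5 with DESeq2 and 6 without the low-count filter. The level of csf1ra (ENSDARG00000102986), a macrophage and pigment cell receptor, was 110 ± 7.87 CPM in CHT-EC and 5.44 ± 2.55 CPM in CHT-HSPC (log2 fold change 4.34, SE 0.42, adjusted p = 0.00812), and the receptors higher in CHT-HSPC were mpl and epor. The list median was 0.45 (camera adjusted p = 0.705), or 0.12 without CHT-HSPC replicate 1 and 0.97 without CHT-HSPC replicate 2. The study candidates klf6a, ccl25b, ccr7 and ccr9a, which the study on these samples is known to have followed up, are a Kruppel-like transcription factor, a chemokine and 2 chemokine receptors. None passed over all genes in the edgeR test, and 2, klf6a and ccl25b, passed when adjusted over the list alone, which is not independent evidence because the list was chosen on these samples. These 2 also had an unadjusted p under 0.05. DESeq2 called the same 2 over all genes, at 0.0400 for klf6a and 0.0420 for ccl25b, while limma-voom called none. The level of klf6a (ENSDARG00000029072) was 302 ± 133 CPM in CHT-EC and 131 ± 39.6 CPM in CHT-HSPC (log2 fold change 1.21, SE 0.38, adjusted p = 0.122, and 0.0012 without the low-count filter). The chemokine ccl25b (ENSDARG00000070873) had 46 and 15 counts in CHT-EC and 0 and 1 in CHT-HSPC, a ratio of 69.9 with a counting interval of 12.1 to 2804 (adjusted p = 0.143). The receptor ccr7 (ENSDARG00000044561) had 26 and 16 counts in CHT-EC and 16 and 90 in CHT-HSPC (log2 fold change −1.05, SE 1.22, adjusted p = 0.655), and its sign turned without CHT-HSPC replicate 2 (0.53). The receptor ccr9a (ENSDARG00000055186) was at 212 ± 11.1 CPM in CHT-EC and 129 ± 68.6 CPM in CHT-HSPC (log2 fold change 0.72, SE 0.39, adjusted p = 0.307).

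None of the 20 Kruppel-like factor genes passed over all genes or over the list alone (edgeR quasi-likelihood test), with a median of 0.32 and a camera adjusted p of 0.141. The median was 0.77 without CHT-HSPC replicate 1 (camera adjusted p = 0.0493), 0.63 without CHT-EC replicate 2 (0.133) and 0.49 without CHT-HSPC replicate 2 (0.359), and 0.62 with the filter of at least 10 CPM. At an unadjusted p under 0.05, 7 were higher in CHT-EC, and DESeq2 placed 4 higher in CHT-EC and limma-voom none. The edgeR test called 6 higher in CHT-EC without the low-count filter, and 1 with the filter of at least 10 CPM, without CHT-HSPC replicate 1 or without CHT-HSPC replicate 2. Of 12 lymphoid genes, tox (ENSDARG00000032317), a nuclear factor of developing T cells, was higher in CHT-EC, at 51.7 ± 9.15 against 11.8 ± 1.17 CPM (log2 fold change 2.13, SE 0.33, adjusted p = 0.0216). The transcription factor bcl11ba (ENSDARG00000062510) was higher in CHT-HSPC, at 124 ± 26.4 against 36.1 ± 0.936 CPM (log2 fold change −1.78, SE 0.28, adjusted p = 0.0237). The counts were the same when adjusted over the list alone, and the lymphoid median of 0.42 was not called by camera (adjusted p = 0.821) and lay at −0.17 without CHT-HSPC replicate 1, 1.03 without CHT-HSPC replicate 2, −0.08 without CHT-EC replicate 1 and −1.64 with the filter of at least 10 CPM. Both calls ended without CHT-EC replicate 1 (0.0750 for tox and 0.135 for bcl11ba) or CHT-EC replicate 2 (0.0703 and 0.0828), and that of bcl11ba also without CHT-HSPC replicate 2 (0.0584).

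Adhesion genes were higher in CHT-EC for 3 of 28 members and higher in CHT-HSPC for 2, and for 5 and 2 when adjusted over the list alone. The level of thy1 (ENSDARG00000035018), a surface glycoprotein, was 49.9 ± 0.431 CPM in CHT-EC and 3.71 ± 0.765 CPM in CHT-HSPC (log2 fold change 3.75, SE 0.37, adjusted p = 0.00821), and the members higher in CHT-HSPC were the integrins itga2b and itgb3b. The list median was 0.86, or 0.18 without CHT-EC replicate 1, and camera did not call it (adjusted p = 0.104, and 0.496 without CHT-EC replicate 1), except without CHT-EC replicate 2 (0.0208). It was 0.52 with the filter of at least 10 CPM. Of 28 basement membrane and matrix genes, 2 were higher in CHT-EC over all genes and 6 when adjusted over the list alone. The level of nid1a (ENSDARG00000068710), the basement membrane linker nidogen, was 94.3 ± 66.8 CPM in CHT-EC and 4.42 ± 0.566 CPM in CHT-HSPC (log2 fold change 4.41, SE 0.58, adjusted p = 0.0140), and that of loxl2b (ENSDARG00000044074), a collagen cross-linking enzyme, was 24.0 ± 11.04 against 2.82 ± 0.179 CPM (log2 fold change 3.08, SE 0.50, adjusted p = 0.0247). The matrix list median was 1.15, with a camera adjusted p of 0.0050 and an adjusted p = 0.72 with an estimated correlation. Camera lost this call without CHT-EC replicate 1 (median 0.25, adjusted p = 0.293) and without CHT-HSPC replicate 2 (0.251), and the median was 1.87 without CHT-HSPC replicate 1. Without CHT-EC replicate 1, 1 adhesion gene and 1 matrix gene were higher in CHT-EC, no adhesion gene was higher in CHT-HSPC, and loxl2b was not past the threshold (0.169). Higher in CHT-EC were 8 matrix genes without CHT-EC replicate 2 and 5 without CHT-HSPC replicate 1. In CHT-EC replicates 1 and 2, nid1a was at 141 and 47.0 CPM and the cartilage and notochord collagen col2a1a at 12606 and 3108 CPM, and the notochord list had a median of 1.77.

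Immediate-early and dissociation stress genes were higher in CHT-EC for 10 of 37 members over all genes and for 23 when adjusted over the list alone. The level of dusp1 (ENSDARG00000100515), a stress-induced phosphatase, was 381 ± 63.5 CPM in CHT-EC and 82.3 ± 1.41 CPM in CHT-HSPC (log2 fold change 2.21, SE 0.26, adjusted p = 0.0117). That of fosb (ENSDARG00000055751), an AP-1 subunit, was 219 ± 87.8 against 57.4 ± 5.71 CPM (log2 fold change 1.93, SE 0.34, adjusted p = 0.0319). For the list as a whole the median was 1.42 (0.92 without CHT-EC replicate 1), with a camera adjusted p of 4.20e-06 and an adjusted p = 0.72 with an estimated correlation. No member passed without CHT-EC replicate 1, where dusp1 had an adjusted p of 0.0539 and fosb one of 0.130, and 6 passed without CHT-HSPC replicate 2, where fosb was lost (0.0607). Of 28 inflammatory signalling genes, 2 were higher in CHT-EC, and 9 were higher in CHT-EC and 1 in CHT-HSPC when adjusted over the list alone. The number higher in CHT-EC over all genes was 1 without CHT-EC replicate 1, 4 without CHT-EC replicate 2, 5 without CHT-HSPC replicate 2, 5 with limma-voom, 5 with the filter of at least 10 CPM, 8 with DESeq2 and 9 without the low-count filter. The cytokine il1b (ENSDARG00000098700) was at 1136 ± 941 CPM in CHT-EC and 45.1 ± 4.66 CPM in CHT-HSPC (log2 fold change 4.65, SE 0.64, adjusted p = 0.0162), with 1801 CPM in CHT-EC replicate 1 and 471 CPM in replicate 2. The flagellin receptor tlr5b (ENSDARG00000052322) was at 78.6 ± 67.3 against 3.83 ± 1.90 CPM (log2 fold change 4.35, SE 0.75, adjusted p = 0.0291, and 0.116 without CHT-EC replicate 1). The inflammatory list median was 0.62, and camera did not call it (adjusted p = 0.131), except without CHT-EC replicate 2 (0.0095) and with the filter of at least 10 CPM (0.0167). This median was 0.0142 without CHT-EC replicate 1, 1.01 without CHT-EC replicate 2 and 0.39 without CHT-HSPC replicate 1. In the same libraries the neutrophil list had a median level of 493 and 281 CPM in CHT-EC and of 31.0 and 65.1 CPM in CHT-HSPC.

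Genes of tissues outside the vessels and blood also differed, mostly toward CHT-EC. Of 18 mesenchyme, cartilage and notochord genes, 4 were higher in CHT-EC over all genes and 7 when adjusted over the list alone. Their median was 1.77 (camera adjusted p = 0.0018, and adjusted p = 0.72 with an estimated correlation), and 1.14 without CHT-EC replicate 1. The level of col2a1a (ENSDARG00000069093), the collagen of cartilage and notochord, was 7857 ± 6715 CPM in CHT-EC and 57.2 ± 23.1 CPM in CHT-HSPC (log2 fold change 7.10, SE 0.79, adjusted p = 0.0103), and it took 1.22% of the counts of CHT-EC replicate 1. That of ta (ENSDARG00000101576), the notochord factor Brachyury, was 215 ± 170 against 3.89 ± 2.36 CPM (log2 fold change 5.79, SE 0.77, adjusted p = 0.0153). Of 18 neural and pigment genes, 8 were higher in CHT-EC over all genes and over the list alone, with a median of 1.59 (camera adjusted p = 0.000972, and adjusted p = 0.52 with an estimated correlation), and 2.41 without CHT-HSPC replicate 1. The 8 neural and pigment genes included tubb5 (ENSDARG00000037997), a neural tubulin, at 38.5 ± 0.688 against 4.14 ± 0.189 CPM (log2 fold change 3.21, SE 0.36, adjusted p = 0.0109), and the neural progenitor factor sox2 (ENSDARG00000070913), at 28.7 ± 4.03 against 3.85 ± 0.900 CPM (log2 fold change 2.90, SE 0.42, adjusted p = 0.0184). Of 17 epidermal genes, 2 were higher in CHT-EC over all genes and 9 when adjusted over the list alone. Their median was 1.83 (camera adjusted p = 0.000213, and adjusted p = 0.72 with an estimated correlation), and 1.21 without CHT-HSPC replicate 2. Those past the threshold over all genes were the keratin genes krt17 (ENSDARG00000094041; 4.13, SE 0.80, adjusted p = 0.0395) and cyt1l (ENSDARG00000036832; 3.22, SE 0.56, adjusted p = 0.0299). The epidermal count over all genes was 1 with totals alone, 4 with upper-quartile factors, 5 with limma-voom, 9 with DESeq2 and 10 without the low-count filter. Without CHT-EC replicate 1 no neural or epidermal gene passed, including tubb5 (0.0541), sox2 (0.0756), krt17 (0.243) and cyt1l (0.118), while 2 notochord and cartilage genes did. Without CHT-EC replicate 2, 4 neural genes passed, sox2 (0.0532) and krt17 (0.0533) not among them, and without CHT-HSPC replicate 1, 7 epidermal genes passed. The call of krt17 also ended with totals alone (0.0549) and limma-voom (0.0802). With the filter of at least 10 CPM, the median was 3.85 for the 6 notochord genes and 2.43 for the 11 neural genes then tested.

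Skeletal muscle genes, by contrast, separated the CHT-HSPC libraries from each other, and by more than any other fixed list did. No member of the 22 passed over all genes or over the list alone in the edgeR test, where 1 had an unadjusted p under 0.05, and neither DESeq2 nor limma-voom called any, while 6 were higher in CHT-HSPC without the low-count filter. The median level was 808 CPM in CHT-HSPC replicate 1 and 113 CPM in replicate 2, against 180 and 307 CPM in CHT-EC. The list median of −0.73 (camera adjusted p = 0.218) was 1.44 without CHT-HSPC replicate 1 (adjusted p = 0.0036) and −1.55 without CHT-HSPC replicate 2, where 7 members were higher in CHT-HSPC (camera adjusted p = 9.62e-08). It was −0.22 without CHT-EC replicate 1 and −1.35 without CHT-EC replicate 2. The muscle actin actc1b (ENSDARG00000099197) was at 2980 ± 3310 CPM in CHT-HSPC and 1826 ± 1009 CPM in CHT-EC (log2 fold change −0.71, SE 0.85, adjusted p = 0.665). Muscle genes took 2.18% of the counts of CHT-HSPC replicate 1 and 0.302% of those of replicate 2. Other lists also differed between these libraries. The epidermal median level was 26.5 CPM in replicate 1 and 5.91 CPM in replicate 2, with a median log2 difference of 1.54. For mitochondrial genes the levels were 1841 and 619 CPM, with a difference of 1.302. Lymphoid genes went the other way, with a difference of −1.99.

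Of the 77 ribosomal protein genes, 70 lay on the CHT-HSPC side, with a median of −0.26 (−0.13 without CHT-HSPC replicate 1), and none passed over all genes or over the list alone with edgeR, where 4 had an unadjusted p under 0.05, nor over all genes with DESeq2 or limma-voom. Camera called the list (adjusted p = 0.0014), but not with an estimated correlation (adjusted p = 0.72) and not with the filter of at least 10 CPM (median −0.13, adjusted p = 0.0692). The most abundant member, rps2 (ENSDARG00000077291), was at 5625 ± 667 CPM in CHT-EC and 6395 ± 821 CPM in CHT-HSPC (log2 fold change −0.19, SE 0.23, adjusted p = 0.670). All 13 mitochondrial genes lay on the CHT-EC side, with a median of 0.63, and none passed over all genes or over the list alone with edgeR, where none had an unadjusted p under 0.05, nor over all genes with DESeq2 or limma-voom. Camera did not call them (adjusted p = 0.0740), except with the filter of at least 10 CPM (0.0147) and without CHT-HSPC replicate 1 (0.000233). Their share of counts was 3.47% and 4.19% in CHT-EC and 3.77% and 1.90% in CHT-HSPC, and without CHT-HSPC replicate 1 the median was 1.34 with 10 members past the threshold, against 0.17 without CHT-HSPC replicate 2 and 0.36 without CHT-EC replicate 2, and 3 members passed without the low-count filter. The level of mt-co1 (ENSDARG00000063905) was 12427 ± 35.1 CPM in CHT-EC and 10757 ± 5631 CPM in CHT-HSPC (log2 fold change 0.21, SE 0.36, adjusted p = 0.774). Its value was 0.88 without CHT-HSPC replicate 1 (0.0259) and −0.21 without CHT-HSPC replicate 2.

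**Figure D3:**
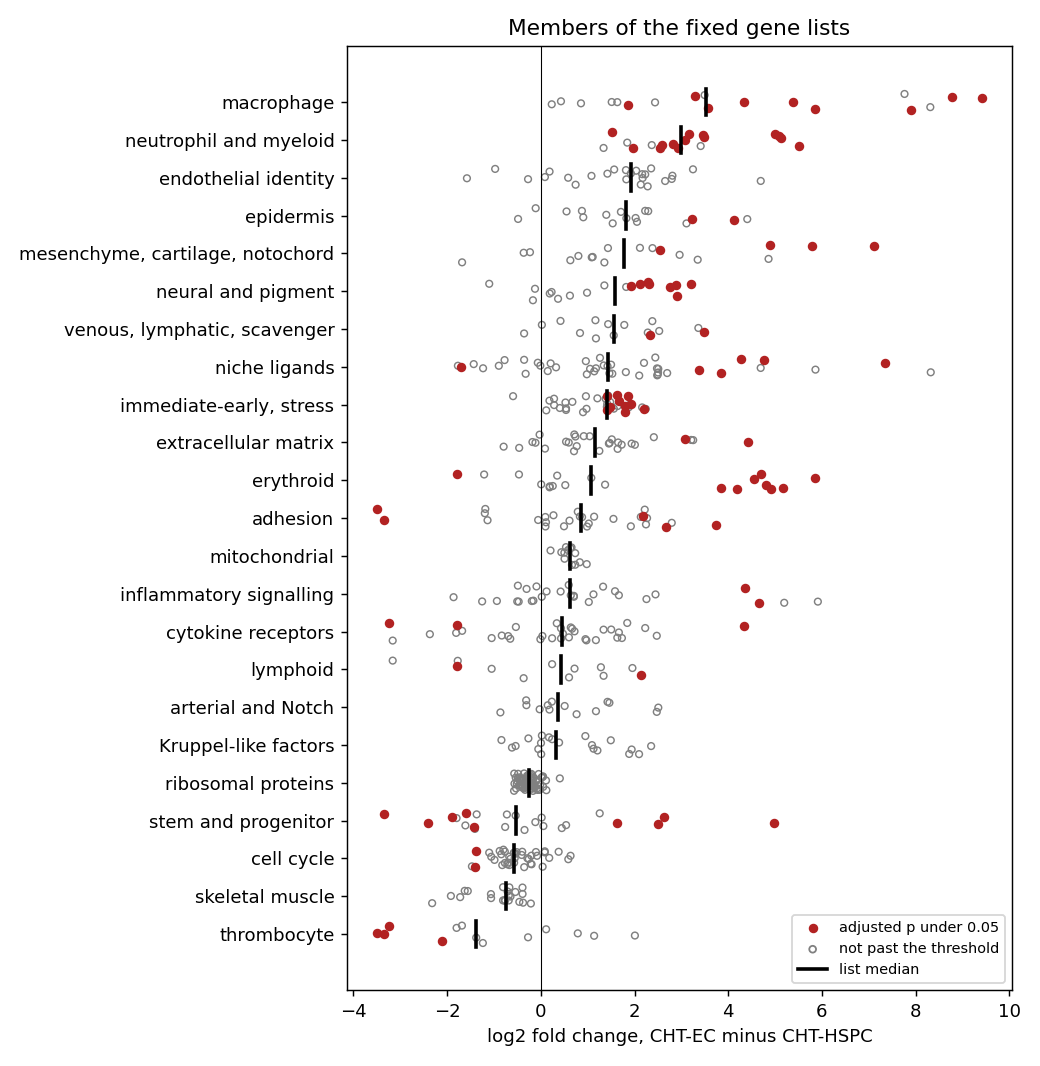
Log2 fold change (CHT-EC minus CHT-HSPC) of each tested member of the fixed gene lists (rows), with filled red points for an adjusted p under 0.05, open points for the others and a black bar at the list median. The macrophage (3.53) and neutrophil (3.0) medians lie farthest toward CHT-EC and the thrombocyte median (−1.38) farthest toward CHT-HSPC.

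Over the 23 lists tested with camera, 11 were higher in CHT-EC (endothelial, venous, erythroid, neutrophil, macrophage, niche, matrix, immediate-early, epidermal, notochord and neural) and 3 were higher in CHT-HSPC (thrombocyte, cell cycle and ribosomal). No call held with an estimated correlation, where no list had an unadjusted p under 0.05. That correlation rests on 2 libraries per group, so the lack of calls does not show that the lists were unchanged. The test fry, which asks whether the genes of a list move on balance in 1 direction, called none. It had 4 lists at an unadjusted p under 0.05 and the smallest adjusted p at 0.0640 for the thrombocyte list. The mixed form of fry lets members move either way. Its unadjusted p ran from 6.57e-05 (neural and pigment) to 0.840 (skeletal muscle), with 0.00415 for the stem and progenitor list.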

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

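Of the settings tried, the counts of list members without each library were chosen after seeing the data. No gene past the threshold changed sign under any setting, but the counts moved. The 718 genes higher in CHT-EC were 471 with totals alone, 2119 without the low-count filter, 2075 with DESeq2, 59 at an adjusted p under 0.01, and 111 to 864 when 1 library was left out. The 143 higher in CHT-HSPC were 812 without the low-count filter, 746 with DESeq2, 233 with limma-voom, 0 at an adjusted p under 0.01 (the main test had 4539 genes of either direction at an unadjusted p under 0.05), and 10 to 139 when 1 library was left out. The share of calls that were higher in CHT-EC was 83.4% in the main test, 72.3% without the low-count filter and 82.1% to 84.3% under the other scalings. Of the main calls, 113 remained without CHT-EC replicate 1, 446 without CHT-EC replicate 2, 566 without CHT-HSPC replicate 1 and 602 without CHT-HSPC replicate 2, where fewer samples entered the fit. Of the 36 named genes past the threshold, these settings ended 22, 9, 3 and 5 calls. The median of all genes was 0.02 in the main test and moved furthest, to 0.15, without CHT-HSPC replicate 2. The 11 lists higher in CHT-EC and 3 higher in CHT-HSPC were 0 and 0 with an estimated correlation and with fry, and 8 to 14 and 3 to 4 when 1 library was left out. The lymphoid median reversed to −1.64 with the filter of at least 10 CPM, where fewer genes were tested. When 1 library was left out, reversals gave ranges of −0.17 to 1.03 for the lymphoid median, 0.12 to 0.97 for the cytokine receptors (where the direction given by camera turned), −1.55 to 1.44 for skeletal muscle, 0.17 to 1.34 for mitochondrial genes (likewise by camera), −1.77 to 0.53 for ccr7, −0.59 to 0.00846 for fli1a, −1.51 to 1.51 for actc1b and −0.21 to 0.88 for mt-co1. The cause was not tested. Of the remaining values, 248 for lists and 525 for named genes kept direction and side of the threshold, with the direction of a list as given by camera. A further 37 and 55 fell short of the threshold, and 8 and 6 newly passed it. The 248 include the lymphoid list without CHT-EC replicate 1, whose median turned to −0.08 while the camera direction stayed. With the replicate number as a block, 813 genes were higher in CHT-EC and 127 in CHT-HSPC, 749 of them shared with the main calls, the calls of mki67 (0.0567) and cenpf (0.0563) ended, and 4 endothelial and 1 arterial list members were higher in CHT-EC. The correlation of deviations was 0.02 for same-numbered and −0.02 for cross-numbered libraries. With 2 libraries per group these are mirror values of a single contrast, so a shared clutch or sort cannot be excluded. At these depths the simulated test called 44 of 100 genes with a log2 change of 2, so many differences of that size would be missed.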

Other observations

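Some genes outside the fixed lists were higher in CHT-HSPC, and those named here were picked after their values were seen, so they stand for no group of genes. The blood group gene kel was at 672 ± 21.2 CPM in CHT-HSPC and 134 ± 26.8 CPM in CHT-EC (n = 2 each, log2 fold change −2.32, SE 0.27, edgeR adjusted p = 0.0116), and rhag, a Rh-associated glycoprotein of red cells, was at 2071 ± 224 against 379 ± 117 CPM (−2.45, SE 0.30, adjusted p = 0.0126). The same held for gata1b (−2.29, adjusted p = 0.0196), a paralog of the red cell factor gata1a, for f2r (−2.20, adjusted p = 0.0225), a thrombin receptor, and for igf1ra (−2.61, adjusted p = 0.0142), an insulin-like growth factor receptor. None of these 5 passed without CHT-EC replicate 1, where the adjusted p lay at 0.0596 for kel, 0.0564 for rhag, 0.0833 for gata1b, 0.0944 for f2r and 0.0972 for igf1ra. In a second set of 16 late red cell genes the calls went the other way, with rhd (2.23, adjusted p = 0.0375), aqp1a.1 (2.07, 0.0219), tspo (1.77, 0.0375) and dmtn (1.56, 0.0405) higher in CHT-EC and none higher in CHT-HSPC (1 had an unadjusted p under 0.05). The calls of rhd (0.0532 to 0.138), tspo (0.0548 to 0.107) and dmtn (0.0837 to 0.147) ended whichever library was left out, and that of aqp1a.1 without CHT-EC replicate 1 (0.0764).

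Toward CHT-EC, genes also picked after their values were seen included epyc, a cartilage matrix proteoglycan, at 477 ± 380 against 3.29 ± 0.356 CPM (7.18, SE 0.70, adjusted p = 0.00821), and cmklr1, a chemerin receptor, at 61.9 ± 30.4 against 0.915 ± 0.231 CPM (6.08, SE 0.54, adjusted p = 0.00761). The cytokine gene il4 had 346 and 599 counts in CHT-EC and none in CHT-HSPC (adjusted p = 0.00945). It was 361-fold higher if CHT-HSPC is set to 3 counts over the group, and the exact binomial interval had a lower limit of 293-fold. These 3 calls held without each library in turn.

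In the weighing of patterns that follows, some tests were chosen after the result was seen. They are those of a lower share of sorted cells, of expression by the kdrl-reporter cells, of the scaling of the CHT-HSPC libraries and of the hemoglobin share.

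Of the list members, 14 of 18 neutrophil, 9 of 18 macrophage and 4 of 18 notochord and mesenchyme genes were higher in CHT-EC (8, 3 and 2 without CHT-EC replicate 1, and no list was called with an estimated correlation), where lyz reached 9320 ± 2489 CPM and kdrl 8.93 ± 7.83 CPM, although the sort on kdrl:mCherry would remove cells without the reporter. A lower share of sorted cells that raised all other cell types alike is argued against, since the list medians of the difference between CHT-EC replicates 1 and 2 were 0.35 for neutrophil and −1.16 for muscle genes, apart by 1.51 with interquartile ranges that did not overlap, while a change in which other cells were present stays open. RNA of neutrophils, which the CHT itself holds, stays open as a candidate source. A second set of 14 neutrophil genes, not looked at before, had a median log2 fold change of 3.07. It was the same with itgam, at 0 counts in CHT-HSPC, at its bound. RNA of notochord and cartilage cells stays open likewise, with 5.47 over 16 genes that include epyc. These second sets rose with the first lists in the same libraries, so they are not independent evidence and cannot tell these sources from others. Expression of the neutrophil genes by kdrl-reporter cells, in a fixed ratio to endothelial genes, stays open, since the answer depends on the endothelial list used. Between the same libraries the endothelial identity list moved by 1.41 (interquartile range 0.882 to 1.88). The neutrophil list moved by 0.35 (0.0945 to 0.541), so these ranges did not overlap. The ranges of the venous list (0.452 to 1.07) and of the arterial list (−0.398 to 1.80) did overlap the neutrophil range. For macrophage and notochord genes such expression also stays open, since their medians of 0.603 and 1.38 had ranges that overlapped that of the endothelial identity list. The ratio of all these transcripts in endothelial cells is not known here, so a ratio that differed between the libraries also stays open.

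Skeletal muscle genes lay a median of 3.01 (log2) higher in CHT-HSPC replicate 1 than in replicate 2. Scaling of the CHT-HSPC libraries is argued against, since a factor per library moves all genes alike and muscle genes moved apart from matched genes. A second set of 28 muscle genes, not looked at before, lay 2.93 higher there. For 10000 random lists of that size, drawn to match it in mean expression, the medians were at most 0.566. TMM centres most genes, so small random medians were set by the method. RNA of muscle cells in CHT-HSPC replicate 1 stays open as a candidate source, although the sort on CD41:GFP would remove muscle cells. The second set rose with the first in the same libraries, so it is not independent evidence. The abundant actc1b was at 5320 CPM in replicate 1 and 639 CPM in replicate 2. No biological explanation was tested, since both libraries belong to 1 group.

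The erythroid list split, with globins, alas2 and cahz higher in CHT-EC and epor higher in CHT-HSPC. A larger share of CHT-EC totals taken by hemoglobin is argued against as the cause of the lower epor, since these shares allow other genes a log2 change of at most −0.0424, while that of epor was −1.78 (SE 0.34). RNA of late red cells in CHT-EC cannot be told apart from other causes, since a second set of 16 late red cell genes had a median of 0.57 with an interquartile range of 0.11 to 1.39, too small and too spread to decide, and the sort on kdrl:mCherry would remove red cells without the reporter. The levels of hbbe1.2 were 2648 and 3768 CPM in the CHT-EC libraries and 66.1 and 45.0 CPM in CHT-HSPC. A difference between the cell types in red cell genes stays open and was not tested.

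Odd and even counts were not equally frequent in all libraries. Among genes with 1 to 100 counts, the share with an even count was 47.7% in CHT-EC replicate 1, 53.8% (95% exact Clopper-Pearson interval 52.6% to 54.9%) in CHT-EC replicate 2, 58.0% (56.9% to 59.1%) in CHT-HSPC replicate 1 and 49.8% in CHT-HSPC replicate 2. In CHT-HSPC replicate 1, 262 genes had a count of 1 and 323 a count of 4, against 1210 and 575 in CHT-EC replicate 1. If fragments were counted more than once in some libraries, counting intervals and floors there would be too narrow, which was not tested.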
